A study of Nannochloropsis oceanica with 16 samples.

How the data were processed

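RNA was sequenced from Nannochloropsis oceanica CCMP1779, a unicellular marine alga with a secondary plastid that is grown for its oil and long-chain fatty acids. Per the labels' protocols, cells grew in flasks of f/2 medium, a seawater-based nutrient mix, at 22 °C and 100 rpm under 12 h of light at 40 µmol photons per s and m2 and 12 h of dark. Biological replicates were collected every 3 h over 1 cycle, at zeitgeber times (ZT, hours after lights on) 0, 3, 6, 9, 12, 15, 18 and 21, with 2 libraries per time and 16 in all. The labels say that ZT0 was collected in the dark, just before lights on, and ZT12 in the light. ZT0 to ZT9 and ZT12 to ZT21 came from 2 incubators set to reversed cycles, so that the incubator cannot be separated from the part of the cycle it supplied. Total RNA was extracted with the Omega eZNA plant kit and libraries were made with the Illumina TruSeq Stranded kit, per the labels' protocols. The series' design text calls the replicates biological without saying whether they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

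The authors deposited 1 table per library of FPKM (fragments per kilobase, scaled to the mapped fragments of the library) with lower and upper confidence limits, in the Cufflinks gene tracking layout per the file headers. TopHat and Cufflinks are named in the submitters' processing notes; their versions, the settings for multiply mapped reads and for strand, and a name for the genome build are not given in the sources used here. Each table listed the same 11973 gene models, all with status OK, on contigs of the strain's own assembly. The deposited gene-model file holds the matching 11973 gene models on 2993 contigs with its own alignment and prediction score per feature, made with MAKER per its source column, and the positions of protein alignments under the prefixes Thaps3, Phatr2, Esi, Phyra1_1, Physo1_1 and PYU1. Those scores were not analysed here.

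The files do not pair gene model IDs with gene names or protein functions. The reference gene table held 160 genes, and 0 of the IDs matched it. The 34 lists of genes by function that had been fixed before the data were examined, photosynthesis, lipid synthesis and cell division among them, could therefore not be formed, and no function is assigned to any gene model. In their place, 7 groups were made from the gene-model file after it was opened and before any value was examined by group. Models were grouped by protein alignments covering at least 0.3 of the coding bases: to Thaps3, Phatr2 or Esi proteins alone, to Phyra1_1, Physo1_1 or PYU1 proteins alone, to both collections, to all 6 prefixes, or to none. The prefixes are those in common use for protein sets of diatoms and a brown alga (the first collection) and of oomycetes (the second), which are relatives of Nannochloropsis among the stramenopiles; the file itself gives only the prefixes. The other groups were single-exon models and models with 5 or more exons.

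The deposited confidence limits equalled FPKM ± 2 FPKM divided by the square root of a number that was whole, within 0.02, for 85.8% to 88.1% of the gene models under 400 in each library. That number was read as the fragments assigned to the model. Summed over models it gave 11516981 to 19975227 fragments per library. In 1 alternative these implied fragments were tested with limma's voom. Gene models of under 200 exonic bases numbered 421; they held 15.3% to 31.8% of the summed FPKM of a library and 0.622% to 1.10% of the implied fragments, so that summed over these models FPKM runs far above the fragment share, though not in each of them. The length behind the listed values, fragments divided by FPKM and library size, followed the genomic span of a model rather than its exonic length (r = 0.991 against 0.878 on the log scale across 5123 models of 3 or more exons with at least 50 fragments). FPKM of models with long introns is therefore low for their exonic length, and fragments from within introns are not told apart; changes between times of 1 model are not altered by the length. Replicate libraries correlated at r of 0.987 to 0.994 across gene models on the log2 scale. Their implied fragments differed by more than sampling noise at each time, with a chi-square per degree of freedom of 6.40 to 16.4, and no pair was identical.

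FPKM as deposited was transformed to log2(FPKM + 1), and 11371 models with a mean of at least 1 FPKM over the 16 libraries were tested; 602 fell below. A fold change on this scale understates the change of weakly expressed genes. Limma fitted the mean of each of the 8 times to all 16 libraries, with 8 residual degrees of freedom, empirical Bayes moderation with a trend (4.62 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05; the contrasts were tested two-sided. Contrasts were a moderated F over the 8 times; the mean of ZT3, ZT6, ZT9 and ZT12 against that of ZT15, ZT18, ZT21 and ZT0 (light against dark); ZT3 against ZT0 (dawn step, within 1 incubator); ZT15 against ZT12 (dusk step, within the other); the 6 other 3 h steps; and the sum of the dawn and dusk steps, which is 0 when the dusk step undoes the dawn step. Rhythm was tested as a cosine and sine of a 24 h period, with the amplitude in log2 units from the mean to the peak and the peak time assigned to the nearest of the 8 sampling times; with 1 sampled cycle this describes a shape and does not test recurrence. Gene groups were tested with limma's camera at an inter-gene correlation of 0.01 and again with an estimated correlation, and peak times with Fisher's exact test.

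Gene models to be named were set by a rule fixed before the data were examined. For light against dark, dawn and dusk it takes the largest log2 fold change in each direction among models with adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and every library of 1 group above every library of the other. The same rule limits it to 2 models per direction where IDs carry no names. Its other parts, for rhythmic genes, gene lists and the highest F, needed gene names and were not used. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, rescaling by median ratio or by quantiles, other moderation, array weights, a replicate block, adjusted p under 0.01, a fold of at least 2, each library left out and other codings of time and incubator. Voom, a block by the letter in the file names, a wider alignment cover of 0.6 and a minimum of 300 exonic bases were added after the data were seen, as were the tests of the gene groups, of peak times and of the light effect between incubators.

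The fits were tested on simulated data built from the real means and spreads, with 200 models changed by 1.5-, 2- or 4-fold. At 2-fold, 95.5% of 67 changed models were recovered for light against dark in a run on 11299 models. Recovery at 2-fold was 91.0% for the dawn step on 11298 models, 89.6% for the dusk step on 11299, 61.2% for dawn against dusk on 11302, 77.6% for change over the cycle on 11295 and 86.6% for a 24 h rhythm (peak over trough) on 11297. At 4-fold, recovery was 93.9% for dawn against dusk and 100% for light against dark. At 1.5-fold it was 94.0% for light against dark and 88.1% for a 24 h rhythm. It was lower at 1.5-fold for the dawn step (58.2%), the dusk step (53.7%), change over the cycle (35.8%) and dawn against dusk (13.4%). False calls made up 1.41% to 7.02% of calls across these simulated comparisons. Only 200 models were changed in each run, while 98.5% were called over the cycle in the real data, so these rates need not hold there. R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.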

Results

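Transcript abundance was measured by RNA sequencing at 8 times of a 12 h light and 12 h dark cycle in Nannochloropsis oceanica CCMP1779, with 2 replicate libraries per time. The design asks which genes change through a light and dark cycle. Depth, read from the deposited confidence limits, was 11516981 to 19975227 fragments per library. The fragments were spread over many genes: between 473 and 767 gene models held 50% of them, and the most abundant model held 1.11% to 4.65%. Gene models are given by their deposited IDs, which the files do not pair with names.

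Nearly the whole transcriptome moved over the cycle. Of 11371 gene models tested, 11205 (98.5%) differed between times, and 9224 of these differed by at least 2-fold between their lowest and highest time means. The range was at least 8-fold in 2322 models and at least 32-fold in 790. The median range was 1.68 log2 units, against a median standard deviation between replicates of 0.13. The remaining 166 models did not pass the test (limma moderated F, adjusted p under 0.05, n = 2 per time).

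More gene models were detected late in the day and early in the night than in the morning. Models at 1 FPKM or more numbered 10417 ± 12.7 (SD, n = 2) at ZT3 and 10619 ± 6.36 at ZT6, then 11070 ± 18.4 at ZT9, 11195 ± 13.4 at ZT12 and 11231 ± 39.6 at ZT15. By ZT21 the number was down to 10654 ± 49.5. A set of 979 models lay below 1 FPKM at ZT3 and at or above it in the mean of ZT12 and ZT15, while 81 went the other way. The 979 gained a median of 16.4 FPKM, and 87.3% of them had no protein alignment, against 70.1% of all gene models. All models are not a like comparison, since the 979 were picked for a low value at ZT3. Tested models without an alignment were also more weakly expressed, with a median of 18.4 FPKM. The median was 31.9 for models aligned to both collections, 29.2 for the diatom and brown alga collection alone and 21.7 for the oomycete collection alone. The share is therefore not read as a trait of models that rise. The excess at ZT12 and ZT15 over ZT3 was 796 models as deposited and 849 after median-ratio rescaling. Quantile normalization gives each library the same distribution, which fixes the excess at 0 in advance and so cannot test it.

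**Figure D1:**
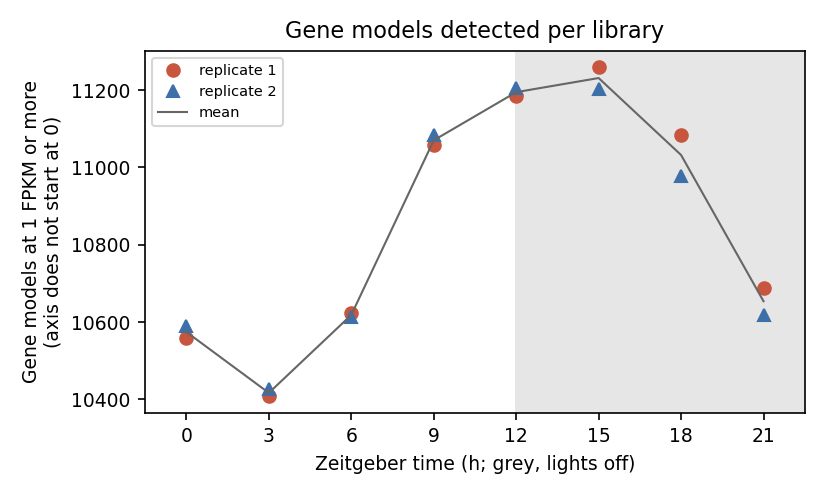
Gene models at 1 FPKM or more (y axis, number of models) in each of the 16 libraries by zeitgeber time (x axis, h; ZT0 was sampled just before lights on), with replicate 1 as circles, replicate 2 as triangles and the mean as a line. Both libraries at ZT3 (10408 and 10426) lie below both at ZT15 (11259 and 11203).

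A 24 h cosine described most of this change. Of the 11371 models, 9850 (86.6%) had a 24 h rhythm, 3420 of them with an amplitude of at least 1 log2 unit, and the median amplitude was 0.75. This fit counts the 16 libraries as separate points. From the 8 time-point means 6988 models were called, and 8476 with the incubator as a term. With the deposited scaling, peaks clustered around the end of the night: 1840 rhythmic models (18.7%) peaked around ZT21 and 1722 (17.5%) around ZT0, against 12.5% for an even spread over the 8 times. The fewest, 811, peaked around ZT15. After median-ratio rescaling the order changed: 1522 peaked around ZT9, 1402 around ZT21, 1186 around ZT0, 1009 around ZT15 and the fewest, 855, around ZT3. Strong rhythms peaked at other hours: of the 3420 models with an amplitude of at least 1, 693 peaked around ZT12, 550 around ZT9 and 512 around ZT15, against 380 around ZT21 and 367 around ZT0, and ZT12 held the most after both rescalings (782 and 580). Models peaking around ZT12 had a median amplitude of 1.52 log2 units and those around ZT15 of 1.32, against 0.57 around ZT0 and 0.55 around ZT3. The time with the lowest mean depended on scaling: ZT12 was lowest for 2843 (25.4%) of the models that changed as deposited and for 2594 after quantile normalization, but for 1347 after median-ratio rescaling, where ZT21 led with 1962. Of rhythmic models with a mean under 5 FPKM, 22.3% peaked around ZT12 and 7.30% around ZT0, against 9.21% and 18.3% of the others. Of these weakly expressed models 51.4% peaked from ZT9 to ZT15 as deposited, 58.1% after median-ratio rescaling and 26.9% after quantile normalization. Peak times come from the limma fit over 16 libraries of 1 cycle. A further 1379 models changed over the cycle without passing the rhythm test.

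**Figure D2:**
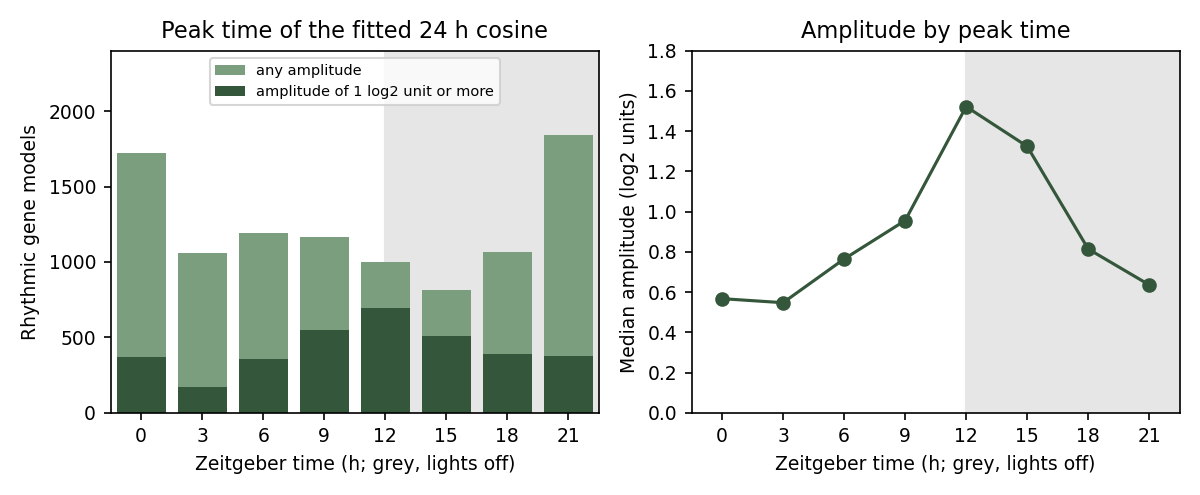
Left, number of rhythmic gene models (y axis) by the sampling time nearest the fitted peak (x axis, h), with those of amplitude 1 log2 unit or more drawn in front as darker bars; right, median amplitude in log2 units by peak time. Bars are highest around ZT21 (1840 models) and lowest around ZT15 (811), while the median amplitude is highest around ZT12 (1.52).

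With the 4 times collected in light set against the 4 collected in dark, 4198 gene models were higher in light and 5480 lower, 1505 and 1478 of them by at least 2-fold. After median-ratio rescaling 4762 were higher and 4906 lower. These counts take the spread between replicates as the error. When the spread between times of one phase was counted as error, in 2 groups of 8 libraries, 2089 models were higher and 2903 lower. With the incubator as a term, 2216 were higher and 3626 lower. This fit still takes the 2 libraries of a time as separate points, so its counts may be too high. NannoCCMP1779|2179 had the largest rise among the models that met the naming rule: it stood at 258 ± 31.9 FPKM (SD, n = 2) at ZT3, 294 ± 29.1 at ZT6 and 90.6 ± 15.7 at ZT12, and between 1.29 and 6.86 at the 4 dark times. NannoCCMP1779|10268 followed almost the same course, from 2.34 ± 0.00431 FPKM at ZT0 to 289 ± 8.79 at ZT6 and back to 4.03 ± 0.309 at ZT15. NannoCCMP1779|5618 ran the reverse course, at 1.15 ± 0.0863 FPKM at ZT9 and 629 ± 33.0 at ZT0. NannoCCMP1779|11685 was highest in the first part of the night, with 477 ± 1.41 FPKM at ZT15 and 460 ± 18.7 at ZT18, then 154 ± 0.550 at ZT21 and 36.4 ± 12.9 at ZT0.

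On the log2 scale, light minus dark was 5.92 ± 0.10 (SE) for NannoCCMP1779|2179 (limma adjusted p = 6.1e-14) and 5.83 ± 0.07 for NannoCCMP1779|10268 (adjusted p = 8.3e-15). It was -6.14 ± 0.08 for NannoCCMP1779|5618 (adjusted p = 2.2e-14) and -4.59 ± 0.09 for NannoCCMP1779|11685 (adjusted p = 9.7e-14). NannoCCMP1779|2179 lies on contig nanno_123 from 86504 to 88201 (plus strand, 2 exons, 1425 coding bases) and has protein alignments under 5 of the 6 prefixes. The other 3 have no such alignment. NannoCCMP1779|10268 is on nanno_83 from 15183 to 17634 (minus strand, 2 exons), NannoCCMP1779|5618 on nanno_182 from 5152 to 6606 (minus strand, 1 exon) and NannoCCMP1779|11685 on nanno_5141 from 122 to 580 (minus strand, 2 exons).

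The same comparison was made within each incubator. In the first, ZT3, ZT6 and ZT9 against ZT0 gave 3827 models higher and 4529 lower in light. In the second, ZT12 against ZT15, ZT18 and ZT21 gave 3463 higher and 5800 lower. Both incubators called 2391 models higher and 3538 lower, against 1165 and 2310 expected for independent lists of the same sizes. Opposite calls, 1114 in all, were fewer than such lists would give. Of these, 698 were higher in the first incubator and lower in the second (1952 expected), and 416 were the reverse (1379 expected). Across genes, which are not independent replicates, the incubators' light effects, which share no library, correlated at r = 0.65. The 4 models named above kept their direction in both. The naming rule fixed this in advance, since it sets every light library on 1 side of every dark library.

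**Figure D3:**
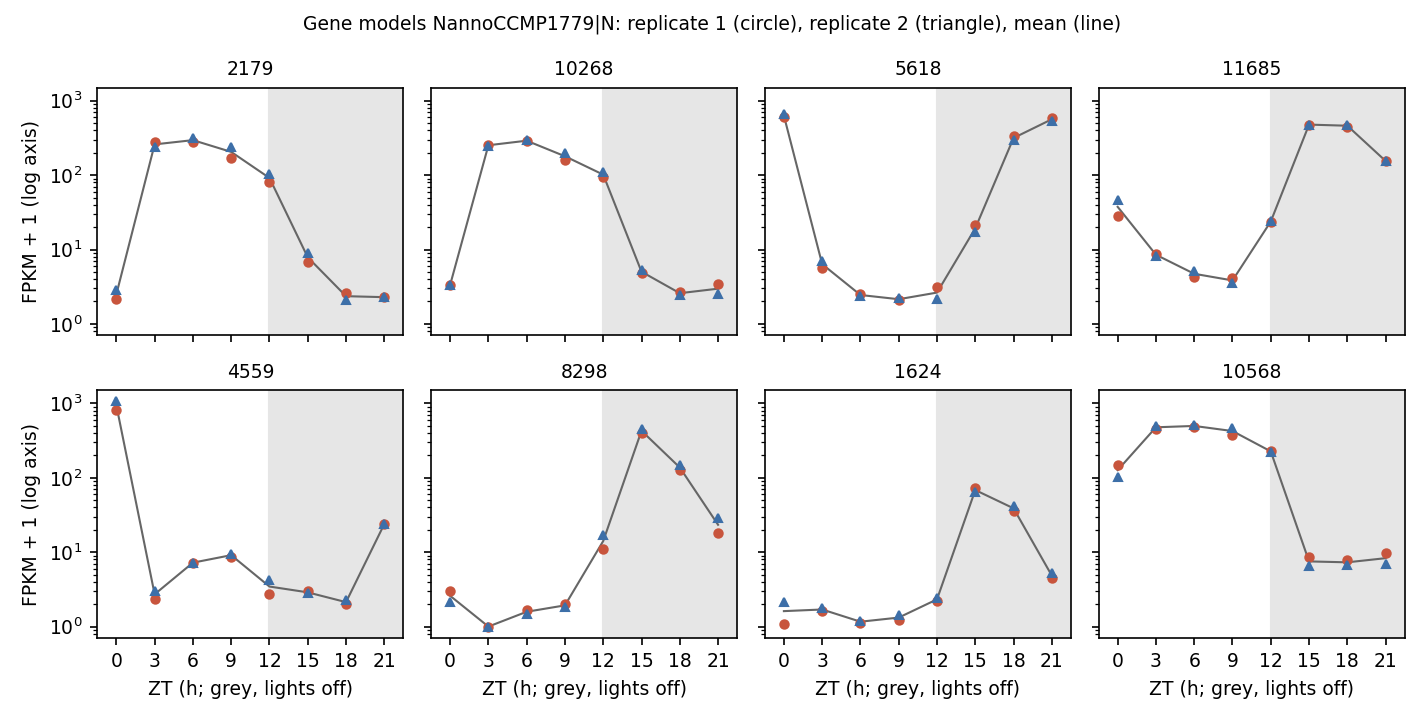
FPKM + 1 (y axis, log scale) by zeitgeber time (x axis, h) for 8 of the 9 gene models named for light against dark, dawn or dusk, with replicate 1 as circles, replicate 2 as triangles and the mean as a line. NannoCCMP1779|2179 and NannoCCMP1779|10268 are high from ZT3 to ZT12, NannoCCMP1779|5618 from ZT18 to ZT0, and NannoCCMP1779|4559 at ZT0, where it reached 942 FPKM.

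Across the dawn step, from just before lights on to 3 h into the light, more models fell than rose with the deposited scaling, and about as many after quantile normalization. Of 5723 changed models, 2286 were higher at ZT3 than at ZT0 and 3437 were lower, 599 and 878 of them by at least 2-fold. NannoCCMP1779|4559 had the largest fall among the models that met the naming rule: it was at 942 ± 170 FPKM (SD, n = 2) at ZT0 and 1.72 ± 0.472 at ZT3, a log2 change of -8.44 ± 0.19 (SE, limma adjusted p = 1.5e-11). At ZT21, 3 h earlier, it had stood at 22.9 ± 0.220 FPKM, and at the 6 times from ZT3 to ZT18 it lay between 1.13 and 8.12. This model lies on nanno_859 from 8545 to 10945 (plus strand, 4 exons, 1119 coding bases). NannoCCMP1779|5618 fell from 629 to 5.36 FPKM (log2 change -6.64 ± 0.17, adjusted p = 5.0e-11). The largest rises that met the naming rule were those of NannoCCMP1779|2179 (6.70 ± 0.20, limma adjusted p = 1.4e-10) and NannoCCMP1779|10268 (6.24 ± 0.14, limma adjusted p = 1.5e-11). Both times came from 1 incubator. The share of higher models among those called was 39.9% as deposited and 50.6% after quantile normalization (2743 higher, 2678 lower).

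The dusk step, from the last sample in light to 3 h into the dark, changed more models than the dawn step did. More rose than fell with the deposited scaling, and fewer after median-ratio rescaling (3564 higher, 3771 lower). Of 7271 changed models, 4101 were higher at ZT15 than at ZT12 and 3170 lower, 1265 and 1401 of them by at least 2-fold. NannoCCMP1779|8298 rose from 13.1 ± 4.41 FPKM (SD, n = 2) to 427 ± 36.2, a log2 change of 4.96 ± 0.23 (SE, limma adjusted p = 2.1e-09). NannoCCMP1779|1624 rose from 1.32 ± 0.137 to 67.4 ± 5.53 FPKM (4.88 ± 0.24, limma adjusted p = 2.5e-09). At ZT21 they stood at 22.4 ± 7.49 and 3.84 ± 0.573 FPKM. NannoCCMP1779|10568, which stayed between 226 and 497 FPKM from ZT3 to ZT12, fell to 6.52 ± 1.48 at ZT15 (-4.93 ± 0.19, limma adjusted p = 7.3e-10). NannoCCMP1779|8298 lies on nanno_3314 from 45 to 930, NannoCCMP1779|1624 on nanno_930 from 2409 to 3210 and NannoCCMP1779|10568 on nanno_1064 from 12334 to 12620, each with 2 exons and no protein alignment. NannoCCMP1779|1624 and NannoCCMP1779|10568 are short, with 189 and 186 exonic bases over spans of 802 and 287 bases. The former had 20 and 15 implied fragments in the ZT12 libraries and 1146 and 784 at ZT15, the latter 561 and 344 at ZT12 and 18 and 10 at ZT15.

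The rule also names NannoCCMP1779|2585 among the models lower at dusk, a single-exon model of 69 bases on nanno_646 from 204 to 272. It was listed at 118 and 183 FPKM in the ZT12 libraries and at 0 in both ZT15 libraries. Each ZT12 value rested on 1 implied fragment, so no fold is given, and voom on the implied fragments did not call it (adjusted p = 0.20). The ZT21 libraries held 428 and 396 implied fragments of it. Rescaling by median ratio moved the median dusk change over all models from 0.09 to -0.01 log2 units.

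Of the 8 steps, the one late in the night changed the fewest gene models. From ZT18 to ZT21, 4162 models changed (4386 after median-ratio rescaling, 4104 after quantile normalization), again the fewest. The step from ZT15 to ZT18 changed the most, 7356, as deposited, ahead of the 7271 of the dusk step. The dusk step came first after median-ratio rescaling, with 7335 against 5675, and after quantile normalization, with 7751 against 6819. The other steps fell between: 5251 models from ZT3 to ZT6, 6659 from ZT6 to ZT9, 6857 from ZT9 to ZT12 and 6793 from ZT21 to ZT0. By changes of at least 2-fold, the dusk step came first with 2666 models, followed by ZT21 to ZT0 with 2268. In the afternoon, from ZT6 to ZT9, 3135 models rose and 3524 fell (3426 and 3272 after median-ratio rescaling), while of those that changed by at least 2-fold 1455 rose and 549 fell. From ZT9 to ZT12, 4786 models were lower and 2071 higher as deposited, and 3041 lower and 3422 higher after median-ratio rescaling (limma, n = 2 per time).

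Directions in several of these steps depended on scaling. From ZT9 to ZT12, 30.2% of the called models were higher as deposited and 52.9% after median-ratio rescaling, which moved the median change of all models from -0.22 to 0.02 log2 units. From ZT15 to ZT18, 73.4% were higher as deposited and 45.8% after that rescaling, with medians of 0.29 and -0.01. From ZT6 to ZT9 quantile normalization moved the median from -0.07 to -0.19, and from ZT18 to ZT21 from -0.06 to 0.07. From ZT18 to ZT21, 36.3% were higher as deposited and 54.7% after quantile normalization. The steps from ZT9 to ZT12 and from ZT21 to ZT0 also crossed from one incubator to the other.

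**Figure D4:**
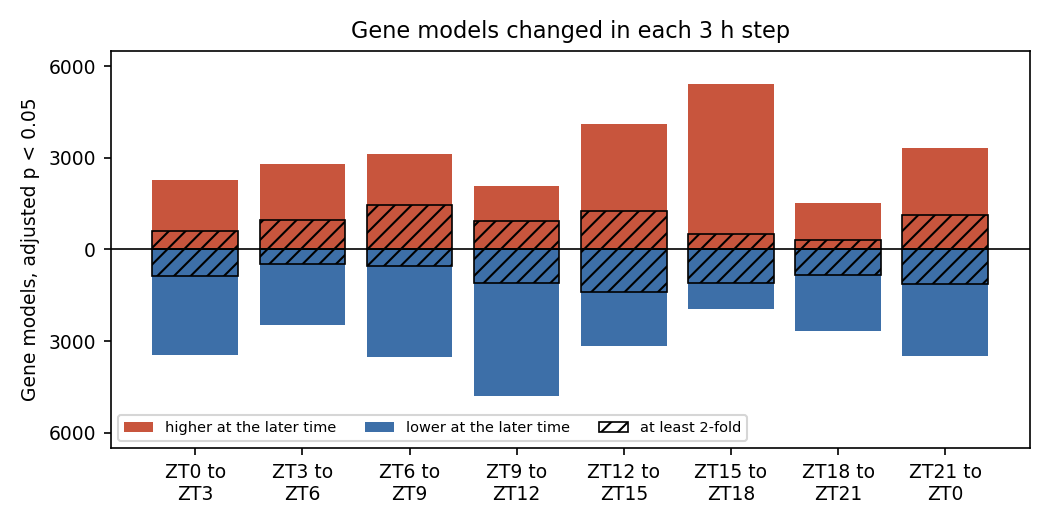
Number of gene models (y axis) called higher (upward bars) or lower (downward bars) at the later time in each 3 h step (x axis), limma adjusted p under 0.05, with the part changed by at least 2-fold hatched. The step from ZT15 to ZT18 has 5399 models higher and 1957 lower with the deposited scaling (2599 and 3076 after median-ratio rescaling), and the step from ZT18 to ZT21 has the fewest calls (4162).

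Reversals between lights-on and lights-off were more frequent than for independent lists, yet most models did not show an exact reversal. Of models higher at dawn, 964 were lower at dusk, against 637 expected for independent lists of the same sizes, a ratio of 1.51 that was 2.57 among changes of at least 2-fold. Of models lower at dawn, 1556 were higher at dusk, against 1240 expected. Models moving the same way at both steps were fewer than independent lists would give: 557 rose at both (824 expected) and 724 fell at both (958 expected). Across genes, which are not independent replicates, the changes of the dawn and dusk steps correlated at r = -0.19 (rho = -0.21), the weakest among the pairs of steps 12 h apart, the others of which correlated at -0.26, -0.36 and -0.43. The sum of both steps, 0 for a gene whose dusk step undoes its dawn step, differed from 0 in 6389 models (56.2%), 3257 of them by at least 2-fold. The dawn and dusk steps share no library.

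Across genes, which are not independent replicates, the time means of ZT18 and ZT21 correlated at r = 0.93, as did ZT0 and ZT3, which differ in light. ZT0 and ZT12 were the least alike of all pairs of times, at r = 0.50. ZT21 and ZT0, from different incubators, correlated at r = 0.90, and ZT9 and ZT12, also from different incubators, at r = 0.84.

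Gene models with and without a listed protein alignment peaked at different times. Only alignments under the listed prefixes were counted, and whether models without one have relatives in other organisms was not tested. Of 7862 tested models without a protein alignment, 6733 were rhythmic, and 21.2% of these peaked around ZT12 or ZT15, against 12.3% of the rhythmic models with an alignment (odds ratio 1.92, 95% interval 1.70 to 2.18, Fisher's exact test p = 6.5e-28, adjusted p = 9.2e-27 over 14 tests). Models aligned to proteins of both collections avoided that part of the cycle, with 10.8% of 1702 rhythmic models peaking there (odds ratio 0.49, adjusted p = 6.9e-20). So did those aligned to the diatom and brown alga collection alone, with 13.6% of 1150 (odds ratio 0.67, adjusted p = 8.8e-06). The end of the night was the reverse. Peaks around ZT21 or ZT0 were found in 42.1% of the rhythmic models aligned to both collections (odds ratio 1.35, adjusted p = 9.3e-08) and in 33.6% of those without an alignment (odds ratio 0.70, adjusted p = 2.3e-14). These tests treat genes as independent, which they are not. The 265 rhythmic models aligned to the oomycete collection alone did not pass either test (adjusted p = 0.41 and 0.35).

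The models aligned to all 6 prefixes are a part of those aligned to both collections: 10.4% of 869 rhythmic models peaked around ZT12 or ZT15 (odds ratio 0.49, adjusted p = 4.2e-11) and 41.5% around ZT21 or ZT0 (odds ratio 1.28, adjusted p = 0.0012, but 0.12 after quantile normalization). Single-exon models had an odds ratio of 1.15 for a peak around ZT12 or ZT15 (adjusted p = 0.037), a call that was lost after median-ratio rescaling (adjusted p = 0.18) and without replicate 1 of ZT9 (0.051) or ZT15 (0.055) or replicate 2 of ZT12 (0.078) or ZT21 (0.074). Models with 5 or more exons did not pass the test (20.4% against 18.1%, adjusted p = 0.077), but did with array weights (adjusted p = 0.025).

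None of the groups passed limma's camera test for the light, dawn or dusk change. Of 21 camera tests (7 groups in 3 comparisons), each adjusted over the 7 groups of its comparison alone, 1 had an unadjusted p under 0.05. It was that of models aligned to all 6 prefixes at dawn (p = 0.021, adjusted p = 0.15, and adjusted p = 0.98 with an estimated correlation). Of those 983 models, 279 rose at dawn and 236 fell, the same numbers when adjusted over the list alone, against 19.3% higher and 30.8% lower among all other models. Of the 1920 models aligned to both collections, 811 rose at dusk and 547 fell (camera adjusted p = 0.64). Of the 7862 models without an alignment, 2997 were higher and 3613 lower in light (camera adjusted p = 0.69).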

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

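The test of the incubator change between ZT21 and ZT0 was chosen after its result was seen, and the test of the light effect between incubators and the splits of the 8 times were added after the data were seen. Dawn and dusk effects differed from mirror images in 6389 gene models by limma's test of the sum of both steps. The sum was 3.16 log2 units for NannoCCMP1779|2179 and 1.91 for NannoCCMP1779|10268, both of which rose by more at dawn than they fell at dusk, and -3.75 for NannoCCMP1779|5618. It was -8.67 for NannoCCMP1779|4559, which fell at dawn with no matching rise at dusk. For NannoCCMP1779|1624 it was 5.03, for NannoCCMP1779|8298 3.60 and for NannoCCMP1779|10568 -2.99. Adjusted p lay between 1.7e-09 and 2.7e-06 for these models (limma, n = 2 per time). Each was named for a large dawn or dusk step, and that step is part of the sum. A sum in the direction of that step is therefore partly built in, and these p-values do not allow for the selection.

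The light effect differed between the incubators in 7496 gene models by limma's test of the difference. Calls in opposite directions, 1114 models, were fewer than independent lists of the same sizes would give. The effect was higher in the first incubator in 4597 of the 7496 and lower in 2899 as deposited, and higher in 3242 and lower in 3909 after median-ratio rescaling. Each incubator supplied other times, so the difference mixes incubator and hour. For NannoCCMP1779|2179 and NannoCCMP1779|10268, the effect in the first incubator minus that in the second was 1.94 and 1.23 log2 units. This difference was -1.75 for NannoCCMP1779|5618 and 1.01 for NannoCCMP1779|11685. Each effect had the same sign in both incubators, which the naming rule fixed in advance.

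With the real times 9678 models were called for light against dark, and of 100 assignments of the 16 libraries to the times, the real one included, 1 reached that number, with 6402 as the highest of the others. This shows only that replicate libraries of a time are alike, since shuffling parts them. It cannot exclude another assignment of replicate pairs to times and does not bear on light and dark. Among the 35 ways to split the 8 times into 4 and 4, 2 called as many: the real split and ZT0, ZT3, ZT18 and ZT21 against the rest, with 9784. A split by incubator called 9412. A chance match of the light and dark hours with other groupings of neighbouring hours therefore cannot be excluded, and the counts point to a structure of the samples by time of day.

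From ZT21 to ZT0 6793 models changed, and from ZT18 to ZT21 4162, although both lie in darkness. The former also crosses the incubators. If the incubator drove the change, its mark would be of opposite sign from ZT9 to ZT12, and the correlation of these steps across genes would lie below that of the other pairs of steps 12 h apart. It was -0.26, between the others (-0.19, -0.36 and -0.43), so an incubator effect and an anticipation of dawn cannot be told apart, because every sample before and after this step differs in both. NannoCCMP1779|4559 rose across this step from 22.9 FPKM at ZT21 to 942 at ZT0, and its fall to 1.72 FPKM at ZT3 took place within 1 incubator. From ZT9 to ZT12, where the incubators change in the other direction, it went from 8.12 to 2.45 FPKM. A lasting difference between the incubators thus does not account for the size of its rise. An incubator effect at that hour alone is not told apart from anticipation.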

How the results depend on the processing

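Among the results and settings given here, tests on implied fragments, the letter in the file names as a block, gene groups, peak odds, neighbours, detected models, the light effect between incubators, alignment cover and exonic length were added after the data were seen; the others were fixed beforehand. Of 1159 values recomputed under alternatives other than leaving out a library, 1093 kept their direction and their side of the threshold, or for counts stayed within 1.5 times the main value. So did 1182 of 1200 values with a library left out, where the lone library of that time was assumed to vary like the others. The 23 and 14 values that reversed were differences of medians near 0 or odds ratios near 1 of gene groups, none of them past the threshold (camera adjusted p = 0.74 to 0.97, Fisher's exact test adjusted p = 0.28 to 1.0); the cause was not tested. With a library left out, the widest range of a count was for the step from ZT3 to ZT6, with 3853 to 5367 models against 5251. For rhythms and peak times, a fold of at least 2 was set on the amplitude from mean to peak (at least 1 log2 unit), not on peak over trough. Requiring a fold of at least 2 reduced the counts by construction, to 3420 rhythmic models (by peak time from ZT0, 367, 171, 357, 550, 693, 512, 390 and 380), 1505 higher and 1478 lower in light, 599 higher and 878 lower at dawn, 1265 higher and 1401 lower at dusk, 3257 for dawn against dusk, 3004 for the light effect between incubators, and, for the other steps in order from ZT3 to ZT6, to 1455, 2004, 2032, 1600, 1126 and 2268. In 2 groups of 8 libraries, where the spread between times counts as error, 2089 models were higher and 2903 lower in light, and 2216 and 3626 with the incubator as a term. Quantile normalization brought the models aligned to all 6 prefixes past the threshold at dawn (difference of medians 0.10, camera adjusted p = 0.047 over the 7 groups of this comparison alone). Over the alternatives this adjusted p ranged from 0.047 to 0.98, and the cause was not tested. The reversed differences at dusk, in log2 units, were for single-exon models -0.0023 (pseudocount 0.1), -0.0013 (mean of at least 5 FPKM), -0.0047 (median ratio), -0.0099 (quantile), -0.0094 (voom) and -0.0018 (300 exonic bases), against 0.0011. For models aligned to the oomycete collection alone they were 0.0074 (mean of at least 5 FPKM), 0.00081 (quantile), 0.0062 (letter block) and 0.00055 (300 exonic bases), against -0.0064, and for models with 5 or more exons 0.0051 (mean of at least 5 FPKM), against -0.011. At dawn, models aligned to the diatom and brown alga collection alone gave -0.011 (pseudocount 5), -0.00061 (no filter) and -0.0059 (letter block), against 0.0024. With a library left out, the ranges that crossed 0 were -0.0045 to 0.018 for the last group, -0.029 to 0.0073 for single-exon models and -0.0099 to 0.039 for models with 5 or more exons at dawn, and -0.015 to 0.0047 for the oomycete collection, -0.0031 to 0.0049 for single-exon models and -0.022 to 0.011 for models with 5 or more exons at dusk. Apart from the models aligned to all 6 prefixes, none of the 679 gene group values changed sides of the threshold. Of 448 odds ratios for peak times 13 lost their call and 1 gained it. Single-exon models around lights-off, at 1.15, were not called with a pseudocount of 0.1 (1.14), a mean of at least 5 FPKM (1.12), median-ratio rescaling (1.09), array weights (1.12), adjusted p under 0.01 (1.17), a fold of at least 2 (1.12), the letter block (1.12) or 300 exonic bases (1.14), nor in 4 of the fits with a library left out (range 1.12 to 1.17). Models aligned to all 6 prefixes lost their call around lights-on after quantile normalization (1.14), and models with 5 or more exons gained one around lights-off with array weights (1.20). Around lights-on, single-exon models turned from 1.01 to 0.997 (pseudocount 5), 0.996 (no filter), 0.996 (mean of at least 5 FPKM), 0.941 (quantile), 0.898 (fold of at least 2) and 0.994 (300 exonic bases), and to between 0.972 and 1.03 with a library left out. The oomycete collection turned from 1.14 to 0.989 (median ratio) and 0.944 (fold of at least 2), and models with 5 or more exons from 0.909 to 1.09 (fold of at least 2); the causes were not tested. NannoCCMP1779|2585 lost its dusk call in voom on implied fragments (adjusted p = 0.20), where 1 fragment per ZT12 library lay behind it; the other 356 values of named models held. Voom called 11050 models changed over the cycle and shared 9361 of its 9488 light calls with the main list of 9678. The 24 h rhythm was called in 8476 models with the incubator as a term and in 6988 from 8 time-point means.

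The replicate block left all 75 values it was run on with the same direction and side of the threshold: with the replicate number as a block, 4204 models were higher and 5489 lower in light, 2330 and 3513 at dawn, 4109 and 3210 at dusk, 11214 changed over the cycle and 9743 were rhythmic. The numbers did not meet the rule for pairing, a correlation over 0.1 in every pair of times: deviations of same-numbered libraries correlated at -0.06 to 0.28 over 28 pairs (median 0.08), 11 of them over 0.1, which leaves a weak shared effect open. The planned tests of 34 gene lists by function were not run, because the IDs carry no names. NannoCCMP1779|1624 and NannoCCMP1779|10568, with under 200 exonic bases, have no value with a minimum of 300. Depth limits the shortest models, such as NannoCCMP1779|2585, where 1 implied fragment stood for 118 FPKM.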

Other observations

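The comparisons by gene orientation, by shared protein and by single maxima were chosen after the data were seen, as was the split by orientation of the test for shared reads; the other tests of explanations were fixed before their own results were seen. Neighbouring genes on a contig shared their time course, and how much depended on their orientation and distance. Over 8237 neighbouring pairs the median correlation of profiles across the 8 times was 0.40 (95% bootstrap interval 0.37 to 0.42), against 0.05 for 9993 random pairs on different contigs. Divergent pairs, transcribed away from each other, had a median of 0.54 (0.51 to 0.57) over 2749 pairs. Tandem pairs had 0.42 (0.37 to 0.46) over 3002 and convergent pairs 0.19 (0.16 to 0.23) over 2486. Mean correlation differed between divergent and convergent pairs by 0.25 and between divergent and tandem pairs by 0.09 (two-sided permutation p = 0.0002 for each, the smallest these permutations can give; pairs share genes and are not independent). Up to 500 bp apart divergent and tandem pairs stood in the reverse order, with 0.63 (0.58 to 0.68) for divergent and 0.82 (0.76 to 0.87) for tandem pairs, while over 500 bp apart they had 0.46 and 0.27. Convergent pairs had 0.15 (0.097 to 0.20) up to 500 bp and 0.077 (0.018 to 0.15) over 500 bp apart, an interval that includes the value of random pairs. Median-ratio rescaling gave 0.49 for divergent and 0.12 for convergent pairs.

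Gene models whose widest alignment, by share of coding bases covered, was to the same protein also ran together. Pairs with the same protein can share models and are then not independent. The 149 such pairs on different contigs had a median profile correlation of 0.78 (95% bootstrap interval 0.52 to 0.88). Of 126 such pairs with both models rhythmic, 61.1% peaked within 3 h of each other, against 27.5% of random pairs, and 8 peaked at least 9 h apart. Copies of near-identical sequence can share reads, so this value is uncertain. Of 896 models at least 2-fold higher at their top time than at any other, and at 10 FPKM or more there, 294 were highest at ZT12, 206 at ZT15, 191 at ZT9 and 159 at ZT0.

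The likeness of neighbours was weighed against technical explanations. Reads shared between touching genes would raise close pairs alone. Pairs over 500 bp apart kept 0.744 of the excess of all neighbours over random pairs, 0.854 among divergent and 0.594 among tandem pairs. That excess includes the far pairs themselves, so a high share is partly built in. Far divergent pairs, at 0.46 (0.42 to 0.50), still lay above random pairs (0.03 to 0.07). So did far tandem pairs, at 0.27 (0.23 to 0.32). Only 4105 of the 11973 gene models include untranslated bases, so transcribed ends may reach into these gaps. Convergent pairs kept 0.199, and the 405 that overlap had a median of 0.63 (0.53 to 0.68), so shared reads remain open as the source of their likeness. Noise shared within a library would vanish across replicates, yet 0.989 of the excess remained when 1 gene was read from replicate 1 and its neighbour from replicate 2. A shared upstream region or chromatin domain remains a hypothesis for divergent and tandem pairs. Tandem pairs up to 500 bp apart, with a median of 0.82, may also share reads or include single genes split into separate models.

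The larger number of models detected around lights-off was weighed in the same way. Peaks of rhythmic models with a mean under 5 FPKM were weighed against scaling alone. Depth and background were not tested for those peaks. For the number of detected models, the tables argue against depth. After thinning each library to the smallest, 0.989 of the excess at ZT9 to ZT18 over ZT0 to ZT6 remained, counted at 1 FPKM or more. An even background of genomic or intergenic reads would lift all genes alike, but the 5th percentile of FPKM at ZT12 and ZT15 was 0.0491 of the median gain of the models that crossed 1 FPKM. For the detected models, the values argue against 1 scale factor per library. The 979 models that crossed 1 FPKM gained a median of 16.4 FPKM, near the library medians of 15.9 to 17.0 at ZT12 and ZT15, and 81 went the other way. Median-ratio rescaling left an excess over ZT3 of 849 models, against 796 as deposited. For rhythmic models under 5 FPKM the deposited scaling stays open. Of these, 51.4% peaked from ZT9 to ZT15 as deposited and 58.1% after median-ratio rescaling. Only 26.9% did after quantile normalization, which met the prediction fixed beforehand for the deposited scaling. That normalization gives libraries equal distributions and would also remove a true rise in many models at once. It therefore cannot tell a real rise of these weakly expressed models around lights-off from a matter of scale.

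Models without a protein alignment might peak around lights-off more often simply because they are weakly expressed. Within 10 equal classes of mean FPKM the common odds ratio was 1.65 (95% interval 1.46 to 1.87), above 1 in 10 of 10 classes, so expression level alone does not account for it.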
